A study of Homo sapiens with 12 samples.

How the data were processed

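RNA of U937 cells was hybridised to 12 one-colour Affymetrix whole-transcript arrays, 3 for each of 4 groups. Per the labels' protocols, total RNA was amplified with a whole-transcript kit and labelled with biotin. The authors deposited 1 value per probe set and array, which were read as log2 intensities from their range, with no value near 0 and a floor near 6. The log base, any offset, the background correction, the summarization and the normalization are not given in the sources used here. Column means lay near 7 and quantiles differed, so the probe set values themselves had not been quantile normalized. Whether such a step came before the summarization is unknown. The medians were 6.50, 6.53 and 6.50 for wild type, 6.54, 6.50 and 6.48 for c-KIT(N822K), 6.46, 6.44 and 6.51 for RUNX1-ETO, and 6.51, 6.49 and 6.51 for both. Scale and centring therefore stay partly unknown, and a fold change of a dim gene is likely compressed by the floor. For arrays, their number limits the precision.

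Of 32321 probe sets, 19158 were listed with 1 gene symbol, 1388 with several and 11775 were unnamed here. By gene ID, 19128 of the single-symbol probe sets matched the RefSeq table, which served only for names. The probe set with the highest mean stood for its gene, giving 18404 genes, of which 637 had more than 1 probe set. No dim genes were removed.

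A model with 1 mean per group was fitted to the deposited values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 3.37 prior degrees of freedom). All 12 arrays shared 1 estimate of spread per gene. Contrasts were the 3 transduced groups against wild type, double-expressing against each single-construct group, the interaction, and a test of any difference. P-values are two-sided and Benjamini-Hochberg adjusted over the genes of a contrast; a gene was called at an adjusted p under 0.05. Errors of fold changes are SE and errors of group means are SD.

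Lists were tested with camera at a preset correlation of 0.01, with adjustment over 34 lists and 6 contrasts together, and again with an estimated correlation and with fry. They covered homologous recombination, Fanconi anaemia, end joining, base excision, mismatch and nucleotide excision repair and their union; damage signalling, p53 targets and the BCL2 family; ERK and STAT5 readouts; cholesterol synthesis, glycolysis and hypoxia, the unfolded protein response and oxidative stress; mitosis, DNA replication, ribosomal proteins, MYC targets, histones and reference genes; stem cell genes, genes reported as induced or repressed by RUNX1-ETO, interferon, inflammatory and MHC class II genes; and markers of neutrophil granules, monocytes, mast cells, erythroid cells, lymphocytes, and fibroblasts and epithelia. Members without a single-symbol probe set were not analysed here.

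The genes named were chosen by a rule fixed before the data were examined. KIT, RUNX1 and RUNX1T1 were always given. Each comparison then named up to 8 called genes with the largest increases and 8 with the largest decreases whose arrays did not overlap between groups, or 5 and 5 for double-expressing against wild type and against c-KIT(N822K) and for the interaction, which had no overlap condition. Up to 4 members with the smallest p followed for each list described. Uncharacterised, small RNA, antisense, pseudogene and sex-linked marker symbols were left out of the largest changes.

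Data were simulated once for RUNX1-ETO against wild type over 18404 genes, with noise from the arrays' residuals. The fit recovered 16 of 50 genes changed by 0.25 on the log2 scale, 40 of 50 changed by 0.5 and 50 of 50 changed by 1. The same set held 50 genes changed by 2 and a list shifted by -0.3. Many changed genes loosen the adjusted threshold, so recovery may be lower where few genes change. Alternatives were quantile normalization, median centring, 2 filters on dim genes, other probe rules, another prior, array weights, fits of the compared arrays alone, 2 stricter thresholds, a block for the replicate number, and leaving out each array. After seeing the data, 2 more were added: leaving out c-KIT(N822K) replicate 3 and RUNX1-ETO replicate 3 together, and a covariate for the array's place on the main within-group axis. That covariate was first taken from the residuals themselves; because residuals are orthogonal to the groups it could not change any fold change, so it was replaced by a projection of the values onto the axis. The simulation of overlaps between lists, with no effect, residual noise of the arrays and lists of the observed lengths taken by rank, was also added after the results were seen; it replaced one in which so few genes were called that no overlap could occur.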

Results

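Gene expression was measured in U937, an established human myelomonocytic cell line that grows in suspension. The 12 arrays fell into 4 groups of 3. One group was untransduced wild type. Another was labelled as expressing c-KIT(N822K), an activated form of the receptor tyrosine kinase c-KIT. The third expressed a truncated form of RUNX1-ETO, the fusion protein made by the t(8;21) translocation of acute myeloid leukaemia that joins RUNX1 to RUNX1T1 (ETO). The fourth was labelled as expressing both. The transduced cells had been sorted, and a group with an empty vector was not analysed here. The series title asks whether an activated c-KIT cooperates with RUNX1-ETO and alters the DNA damage seen with it. Each array gave 32321 values, with medians of 6.44 to 6.54 and a floor near 6, and 18404 genes were tested. The number of arrays limits the precision. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays.

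The introduced genes were read first. RUNX1T1, the ETO partner, stood at 7.12 ± 0.13 (SD, n = 3) in RUNX1-ETO cells and 7.15 ± 0.01 in cells with both constructs, against 6.65 ± 0.09 in wild type and 6.55 ± 0.08 in c-KIT(N822K) cells. RUNX1T1 was higher by 0.47 ± 0.07 (SE) in RUNX1-ETO than in wild type (limma, adjusted p = 0.0311), and all 6 arrays labelled with the fusion lay above the other 6. With 1 array left out the RUNX1T1 difference ranged from 0.39 to 0.51 and was called in 3 of 12 fits, those without c-KIT(N822K) replicates 1 or 3 or RUNX1-ETO replicate 3; the highest adjusted p was 0.206, without wild-type replicate 1. RUNX1 itself did not pass the test: its log2 difference was 0.12 ± 0.08 for RUNX1-ETO against wild type (adjusted p = 1.0) and 0.34 ± 0.08 for both constructs against wild type (adjusted p = 0.085). The KIT probe set did not mark the arrays labelled c-KIT(N822K). KIT stood at 6.29 ± 0.04 in wild type, 6.32 ± 0.05 on the arrays labelled c-KIT(N822K), 6.25 ± 0.15 with RUNX1-ETO and 6.33 ± 0.04 with both. KIT differed by 0.04 ± 0.07 between the c-KIT(N822K) and wild-type arrays (adjusted p = 0.982). Every direction attributed to c-KIT(N822K) in the text therefore rests on the array labels.

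**Figure D1:**
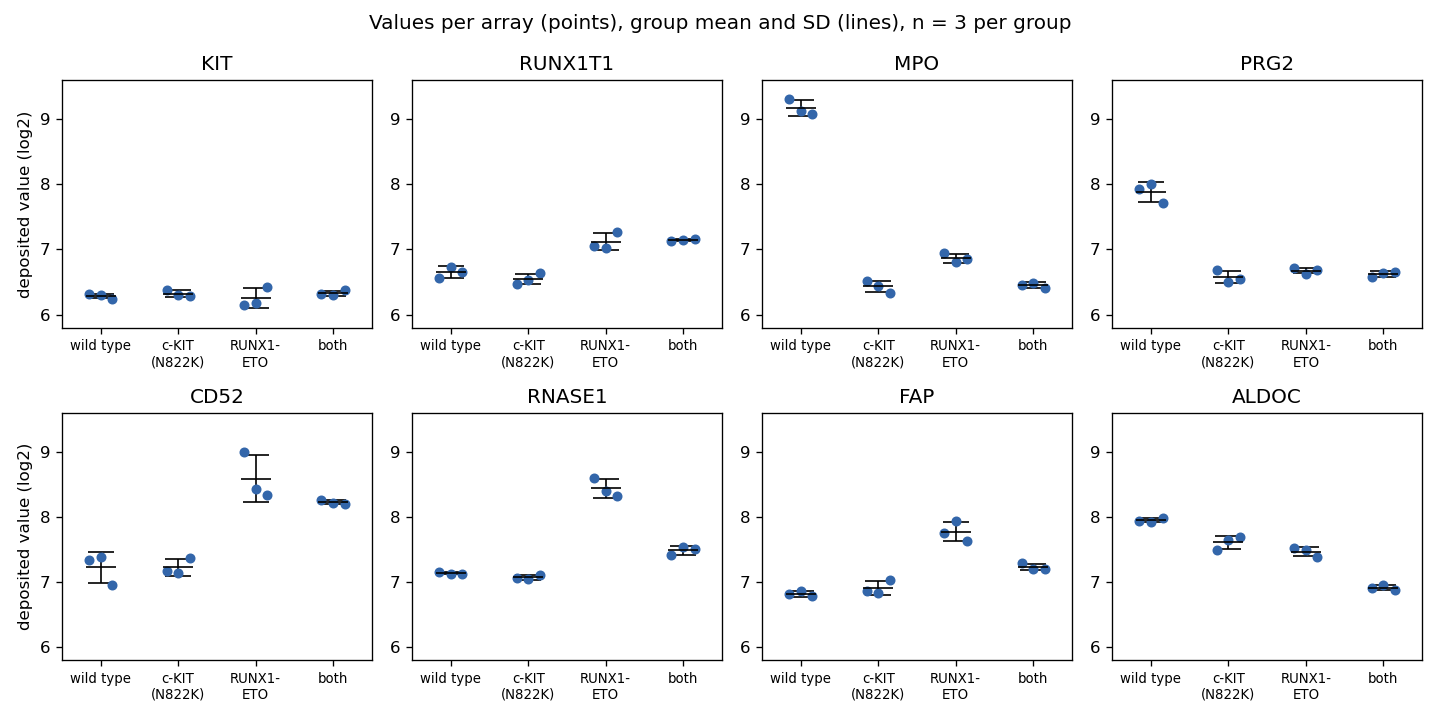
Deposited log2 values of 8 genes on each of the 12 arrays, by group, with points for arrays and lines for the group mean and SD (n = 3). KIT lies near 6.3 in every group, RUNX1T1 is raised in both groups with the fusion, and MPO falls from a wild-type mean of 9.17 to between 6.43 and 6.86 in the 3 transduced groups.

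In the arrays labelled c-KIT(N822K), 7 genes were lower than in wild type and 0 were higher. MPO, the myeloperoxidase of primary granules, was at least 6.68-fold lower (log2 fold change -2.74 ± 0.07 SE, n = 3 per group, adjusted p = 2.17e-09). PRG2, the eosinophil granule major basic protein, was at least 2.47-fold lower (-1.30 ± 0.07, adjusted p = 9.16e-06). Both are lower bounds, since the means of these genes on the c-KIT(N822K) arrays, 6.43 and 6.58, lay near the floor of the arrays. The others were the mitophagy receptor BNIP3L (-0.56 ± 0.07), the histone gene H2AC8 (-0.48 ± 0.07), the adhesion molecule ALCAM (-0.44 ± 0.06), the NADPH oxidase subunit CYBB (-0.32 ± 0.04) and the serine protease PRSS21 (-0.30 ± 0.04). MPO was the 1 called member of the 15 primary granule genes; CTSG (0.26 ± 0.10), DEFA4 (-0.17 ± 0.08) and SERPINB1 (-0.27 ± 0.12) did not pass. At an unadjusted p under 0.05, limma gave 894 genes, 86 higher and 808 lower, where chance gives 920.2. MPO and PRG2 were called whichever single array was left out, and the other 5 were each lost in at least 1 such fit. There were 2 calls without wild-type replicate 2, c-KIT(N822K) replicate 1 or c-KIT(N822K) replicate 2, 3 without wild-type replicate 1, RUNX1-ETO replicate 1 or double-expressing replicate 2, and 4 without wild-type replicate 3, RUNX1-ETO replicate 2 or double-expressing replicate 1. Without c-KIT(N822K) replicate 3 there were 7, 2 of them higher.

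Several gene lists fixed before the data were examined were called in the same comparison by camera with a preset inter-gene correlation. Of all 204 tests of 34 lists in 6 contrasts, 75 were called this way. In simulated data with no shifted list and the arrays' own correlated noise, the same test called a median of 58 of 204, between 9 and 95 over 20 draws. With an estimated correlation, 1 of the 204 was called, the interferon list in RUNX1-ETO against wild type. The 17 measured cholesterol synthesis genes were lower in c-KIT(N822K) arrays (median -0.19, adjusted p = 3.1e-07; adjusted p = 0.395 with an estimated correlation). Of the 17, limma called 0 over all genes, 6 were lower and 0 higher at an unadjusted p under 0.05, and 2 were lower when adjusted over the list alone: INSIG1 (-0.38 ± 0.07), a feedback regulator of sterol synthesis, and CYP51A1 (-0.45 ± 0.11, and -0.19 with the mean of its probe sets). The glycolysis and hypoxia list was lower as well (median -0.084, adjusted p = 0.000842; adjusted p = 0.455 with an estimated correlation), with BNIP3L called of 27 and 3 lower adjusted over the list alone; without c-KIT(N822K) replicate 1 the list had adjusted p = 0.0762. ERK feedback genes (median -0.027, adjusted p = 0.337, and 0.0208 without c-KIT(N822K) replicate 2) and STAT5 response genes (median -0.032, adjusted p = 0.402), 2 readouts of kinase signalling, were not called with all arrays. Of the ERK list, EGR1 had -0.41 ± 0.11 and MYC 0.18 ± 0.11, neither past the test.

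Between RUNX1-ETO and wild-type cells 15 genes differed, 7 higher and 8 lower with RUNX1-ETO. The lymphocyte and monocyte surface antigen CD52 was 2.57-fold higher (1.36 ± 0.16, adjusted p = 0.00643), the secreted ribonuclease RNASE1 2.47-fold higher (1.31 ± 0.06, adjusted p = 2.78e-06) and the membrane protease FAP 1.94-fold higher (0.96 ± 0.07, adjusted p = 0.000163). ALOX5AP, which leukotriene synthesis needs, was higher by 0.65 ± 0.09, the antiviral OAS1 by 0.35 ± 0.05 and the splicing factor SNRPD2 by 0.31 ± 0.04. After quantile normalization the SNRPD2 difference was 0.030 and no longer called. MPO was at least 4.95-fold lower (-2.31 ± 0.07, adjusted p = 1.51e-08) and PRG2 at least 2.30-fold lower (-1.20 ± 0.07), lower bounds since the floor near 6 adds to the RUNX1-ETO means of 6.86 and 6.68. H2AC8 (-0.49 ± 0.07), the glycolytic aldolase ALDOC (-0.49 ± 0.06), the transcription factor NFE2 (-0.40 ± 0.05), CYBB (-0.32 ± 0.04), SLAIN1 (-0.30 ± 0.05) and PRSS21 (-0.29 ± 0.04) were lower too. MPO, PRG2, H2AC8, CYBB and PRSS21 were 5 genes lower in both this comparison and c-KIT(N822K) against wild type, where independent lists would share 0.00304. In 100 simulated sets with no effect, the same shared wild-type arrays and lists of the same lengths taken by rank, the overlap was 0.90 on average and up to 7, and 3 sets reached 5. MPO, PRG2, RNASE1, FAP, CD52 and ALDOC were called whichever single array was left out, and each of the other 9 was lost in at least 1 such fit. There were 64 calls without RUNX1-ETO replicate 3, 50 higher and 14 lower, 6 without RUNX1-ETO replicate 1, 7 without RUNX1-ETO replicate 2 or wild-type replicates 1 or 2, 8 without double-expressing replicate 2 and 9 without c-KIT(N822K) replicate 2. Quantile normalization gave 35, of which 22 were higher and 13 lower.

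Type I interferon response genes were higher in RUNX1-ETO cells (26 measured, median 0.033, adjusted p = 1.3e-09; adjusted p = 0.0347 with an estimated correlation). OAS1 was called over all genes and 6 were higher adjusted over the list alone, among them IFIT1 (0.35 ± 0.07), IFI6 (0.58 ± 0.12) and ISG15 (0.53 ± 0.12). Monocyte and macrophage genes were higher as a list of 22 (median 0.034, adjusted p = 0.00239; adjusted p = 0.342 with an estimated correlation), although CYBB, its 1 called member, was lower; LYZ (0.56 ± 0.13, and 0.30 after quantile normalization), CD68 (0.36 ± 0.09) and S100A9 (0.58 ± 0.19) were among the 4 higher adjusted over the list alone. Of 10 genes that others have reported as repressed by RUNX1-ETO, MPO and NFE2 were lower (list median -0.051, adjusted p = 5.22e-05; adjusted p = 0.103 with an estimated correlation), and LAT2 had -0.33 ± 0.08 (adjusted p = 0.275). In c-KIT(N822K) arrays the list was also called by camera (median -0.091, adjusted p = 0.00164), with MPO the 1 called member. That call was lost with an estimated correlation (adjusted p = 0.170) and after quantile normalization (adjusted p = 0.121). Whether the list differed between the fusion and c-KIT(N822K) was not tested. The list reported as induced by RUNX1-ETO was not called (median -0.073, adjusted p = 0.307), with CCND2 at -0.42 ± 0.07 (adjusted p = 0.0754) and CDKN1A at 0.22 ± 0.05 (adjusted p = 0.228). The 8 MHC class II genes were lower (median -0.092, adjusted p = 0.00175; adjusted p = 0.342 with an estimated correlation), HLA-DPA1 by -0.53 ± 0.11 and HLA-DMA by -0.27 ± 0.06, both past the test over the list alone. Ribosomal protein genes were higher (32 measured, median 0.31, 23 adjusted over the list alone; adjusted p = 0.0946 with an estimated correlation). limma called 0 of them over all genes, with 23 higher at an unadjusted p under 0.05, and after quantile normalization their median was 0.011 (adjusted p = 0.899). The 14 measured reference genes, fixed as a control list, were higher in the same comparison (median 0.13, adjusted p = 1.83e-05; adjusted p = 0.395 with an estimated correlation), and after quantile normalization their median was -0.0068 (adjusted p = 0.793).

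DNA repair, chosen because the series title names DNA damage, was tested as 95 measured genes of 6 pathways. No single repair gene was called by limma in any of the 5 pairwise comparisons. In RUNX1-ETO against wild type the repair genes were not called together (median -0.043, adjusted p = 0.619; 4 of 95 lower and 0 higher at an unadjusted p under 0.05), and the smallest p-values were those of FAN1 (-0.17 ± 0.04), EME1 (-0.18 ± 0.05) and FANCG (-0.19 ± 0.05). In double-expressing against RUNX1-ETO cells their median was -0.098 (adjusted p = 0.00214; adjusted p = 0.756 with an estimated correlation), with 11 lower and 6 higher at an unadjusted p under 0.05. With the within-group axis as a covariate it turned to 0.020 (adjusted p = 0.697), and the call was lost after quantile normalization (median -0.044, adjusted p = 0.297) and without the dimmest 30% (adjusted p = 0.109). RUNX1-ETO against wild type was called with that covariate (median -0.049, adjusted p = 0.0371). The direction in RUNX1-ETO against wild type turned without RUNX1-ETO replicate 3 (median 0.049, adjusted p = 0.00419), the list was called lower without RUNX1-ETO replicate 2 (median -0.066, adjusted p = 0.000817), and the call in double-expressing against RUNX1-ETO cells was lost without RUNX1-ETO replicate 2 (median -0.037, adjusted p = 0.307). In c-KIT(N822K) arrays against wild type their median was -0.060 (adjusted p = 0.00118; adjusted p = 0.751 with an estimated correlation), a call lost without c-KIT(N822K) replicate 1 (median -0.020), after quantile normalization (median 0.0022), without the dimmest 30% (adjusted p = 0.180) and with the within-group axis as a covariate (median -0.028, adjusted p = 0.366). In double-expressing against wild-type cells their median was -0.10 (adjusted p = 0.000538; adjusted p = 0.737 with an estimated correlation), and with that covariate -0.041 (adjusted p = 0.256). There the end joining factor PAXX (0.37 ± 0.08) and MNAT1 (-0.28 ± 0.07), RFC5 (-0.35 ± 0.09) and XRCC4 (-0.24 ± 0.06) were among the 5 lower and 2 higher adjusted over the list alone.

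DNA damage signalling genes were lower in double-expressing than in wild-type cells (20 measured, median -0.13, adjusted p = 0.00118; adjusted p = 0.577 with an estimated correlation). CDC25C, a phosphatase that drives entry into mitosis, was the 1 called member (-0.22 ± 0.04, adjusted p = 0.0445), and WEE1 (-0.24 ± 0.06, and -0.13 with the mean of its probe sets), ATM (-0.41 ± 0.10) and CHEK2 (-0.37 ± 0.11) passed over the list alone. In double-expressing against RUNX1-ETO cells the list median was -0.15, called by camera with the preset correlation. That call was lost with an estimated correlation (adjusted p = 0.455) and with fry (adjusted p = 0.311). p53 target genes were not called in RUNX1-ETO against wild type (median -0.0034 with the test directed upward, adjusted p = 0.327) nor in double-expressing against RUNX1-ETO cells (median -0.0019, adjusted p = 0.716). In double-expressing against wild-type cells their median was -0.0079 (adjusted p = 0.826), and CDKN1A, a cell cycle inhibitor, was the 1 called member of 23, higher by 0.38 ± 0.05 (adjusted p = 0.0102), and was not called without wild-type replicate 1 or double-expressing replicate 2.

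Cells with both constructs differed from wild type at 173 genes, 45 higher and 128 lower; without double-expressing replicate 1 there were 334, 204 higher and 130 lower, so the balance of directions rested on that array. MPO (-2.72 ± 0.07, adjusted p = 2.35e-09) and PRG2 (-1.26 ± 0.07, adjusted p = 9.1e-06) were lower as with 1 construct, again with means near the floor (6.45 and 6.62). ALDOC was 2.05-fold lower (-1.04 ± 0.06, adjusted p = 6.48e-06) and BNIP3L 1.97-fold lower (-0.98 ± 0.07, adjusted p = 5.72e-05). The sterol synthesis gene ERG28 was lower by -0.94 ± 0.14. The ubiquitin-conjugating enzyme UBE2S (1.04 ± 0.18), CD52 (1.00 ± 0.16), NOSIP (0.90 ± 0.13), the glutathione peroxidase GPX1 (0.79 ± 0.15) and the proteasome receptor ADRM1 (0.72 ± 0.13) were higher. Of the 7 genes lower in c-KIT(N822K) arrays, all 7 were lower here, and of the 15 RUNX1-ETO calls, 4 were higher and 8 lower here too. Independent lists would share 0.0487 genes for the first overlap and 0.0171 and 0.0556 for the second. These comparisons share the wild-type arrays, which part of the overlap may come from: in 100 simulated sets with no effect and lists of the same lengths, 8 sets reached the first overlap, 14 the 4 higher and 7 the 8 lower. Of the genes named for this comparison, MPO, PRG2, ALDOC, BNIP3L, INSIG1, P4HA1 and HLA-DMA were called whichever single array was left out. There were 16 calls without double-expressing replicate 3, 17, 39 and 46 without wild-type replicates 1, 2 and 3, 22 without double-expressing replicate 2, 292 without c-KIT(N822K) replicate 1 and 432 without RUNX1-ETO replicate 3. With each array centred on its median, 45 genes were called, 17 higher and 28 lower.

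Genes of the cholesterol synthesis list and of the glycolysis and hypoxia list made up part of this difference. Of 17 cholesterol genes, 5 were called lower and 12 were lower adjusted over the list alone (median -0.31, adjusted p = 1.97e-11; adjusted p = 0.342 with an estimated correlation). They included INSIG1 (-0.80 ± 0.07, adjusted p = 0.000439), CYP51A1 (-0.76 ± 0.11), MSMO1 (-0.90 ± 0.13) and HMGCS1 (-0.89 ± 0.17). With the mean of each gene's probe sets CYP51A1 was at -0.38 and still called. Of 27 glycolysis and hypoxia genes, 7 were called lower, and adjusted over the list alone 12 were lower and 2, ALDOA and ENO1, named after their values were seen, higher (median -0.073, adjusted p = 2.04e-05; adjusted p = 0.342 with an estimated correlation). P4HA1, a collagen prolyl hydroxylase, had -0.89 ± 0.11 and the glucose transporter SLC2A3 -0.76 ± 0.12, beside ALDOC and BNIP3L. The remaining called members were BNIP3, NDRG1 and ANKRD37, named after they were seen. Among the called members of this list, ALDOC alone is a glycolytic enzyme. Of the 8 MHC class II genes, HLA-DMA (-0.55 ± 0.06) and HLA-DPA1 (-0.81 ± 0.11) were called lower (list adjusted p = 0.00403; adjusted p = 0.342 with an estimated correlation, and 0.0910 with the mean of each gene's probe sets). With that mean HLA-DMA was at -0.17 and not called (adjusted p = 0.469), and HLA-DPA1 was not called without wild-type replicate 1 or double-expressing replicate 3 (highest adjusted p 0.0629). HLA-DRB5, a class II gene outside the list, was called lower too (-0.63 ± 0.06, adjusted p = 0.00163, named after it was seen). Of the primary granule genes, MPO and MS4A3 (-0.57 ± 0.10) were called lower. No member was called higher, and CEBPE (0.52 ± 0.11, adjusted p = 0.0523) did not pass. By fry the cholesterol, glycolysis and hypoxia, MHC class II and primary granule lists were called in this comparison. The granule list had a median of only -0.024. ELANE (0.34 ± 0.20), PRTN3 (0.43 ± 0.21), AZU1 (0.19 ± 0.15) and CTSG (0.12 ± 0.10) were not called. Whether the fry call of the granule list rests on MPO was not tested. RPS9 (0.48 ± 0.06), RPL8 (0.54 ± 0.09), RPL18 (0.38 ± 0.07) and RPS19 (0.37 ± 0.07) were the 4 genes called higher of the 32 on the ribosomal protein list. RPL36 (0.65 ± 0.10) and RPL29 (0.38 ± 0.06), outside the list and named after they were seen, were called higher too. After quantile normalization the median of that list was 0.0080 (adjusted p = 0.754), and RPL18 (0.21) and RPS19 (0.18) were no longer called; RPS9 was lost with the mean of its probe sets (0.27).

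**Figure D2:**
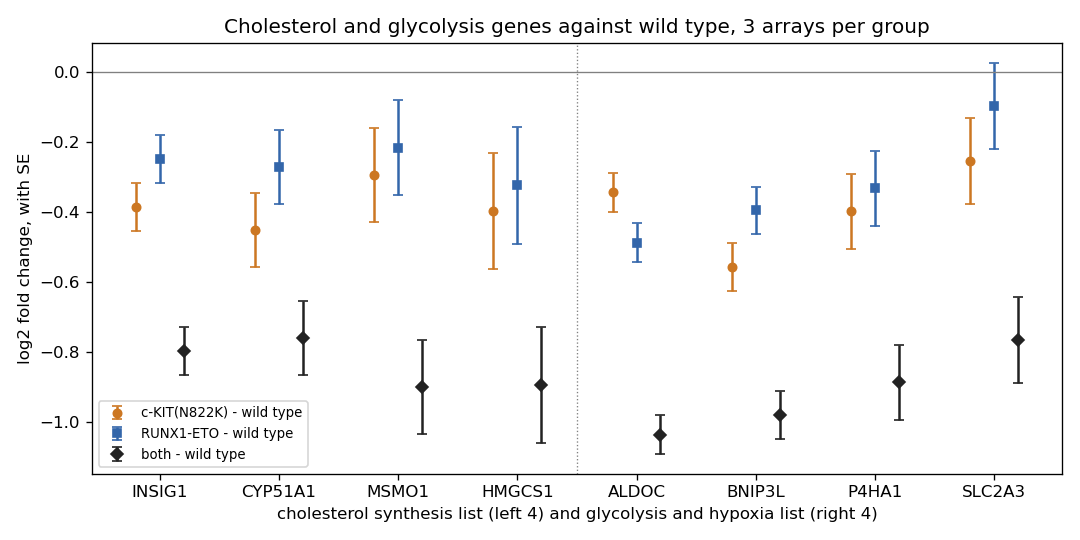
Log2 fold changes against wild type, with SE, of 4 cholesterol synthesis genes and 4 glycolysis and hypoxia genes in c-KIT(N822K), RUNX1-ETO and double-expressing cells (3 arrays per group). In double-expressing cells the 8 genes lie between -0.76 (SLC2A3 and CYP51A1) and -1.04 (ALDOC), below both single-construct values of the same gene. They were picked for the smallest p of their list in double-expressing against wild-type cells, which favours this order. The full lists had medians of -0.31 and -0.073 there.

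The comparison of double-expressing with RUNX1-ETO cells asks what c-KIT(N822K) adds to the fusion. Here 6 genes were called, 1 higher and 5 lower, but the direction depended on single arrays: there were 70, 53 higher and 17 lower, without double-expressing replicate 1, and 204, 25 higher and 179 lower, without RUNX1-ETO replicate 3. RNASE1 was 1.93-fold lower (-0.95 ± 0.06, adjusted p = 0.000183) and FAP 1.45-fold lower (-0.54 ± 0.07, adjusted p = 0.0367), both higher with RUNX1-ETO alone than in wild type. Both stayed above wild type in double-expressing cells, RNASE1 by 0.36 ± 0.06 (adjusted p = 0.0316) and FAP by 0.42 ± 0.07 (adjusted p = 0.0287), values named after they were seen; each was called in 7 of 12 fits with 1 array left out (highest adjusted p 0.148 and 0.122). These were 2 of the 15 RUNX1-ETO calls, called the opposite way. Without RUNX1-ETO replicate 3 the count was 15 of 64 RUNX1-ETO calls. It was 1 without RUNX1-ETO replicates 1 or 2, any wild-type replicate, c-KIT(N822K) replicate 2 or double-expressing replicates 2 or 3. Both comparisons share the RUNX1-ETO arrays with opposite sign. In 100 simulated sets with no effect and lists of the same lengths taken by rank, the count was 0.86 on average and up to 5, and 21 sets reached 2. BNIP3L (-0.58 ± 0.07), INSIG1 (-0.55 ± 0.07) and ALDOC (-0.55 ± 0.06) were also lower, and the sialyltransferase ST6GALNAC6 was higher (0.59 ± 0.07, adjusted p = 0.0163; 0.30 and not called with the mean of its probe sets). OAS1 had -0.33 ± 0.05 (adjusted p = 0.0672), and its interferon list was lower (median -0.048, adjusted p = 0.0037; adjusted p = 0.209 with an estimated correlation). Cholesterol genes were lower too (median -0.23, 1 of 17 called, 7 lower adjusted over the list alone, adjusted p = 0.393 with an estimated correlation). So were glycolysis and hypoxia genes (median -0.053, 2 of 27 called, 8 over the list alone, adjusted p = 0.379 with an estimated correlation). The reference genes were lower as well (median -0.20, adjusted p = 0.000104, but 0.455 with an estimated correlation and 0.142 after quantile normalization). RNASE1 was called whichever single array was left out, with 1 call without RUNX1-ETO replicate 2 or double-expressing replicate 3, 2 without double-expressing replicate 2, 3 without RUNX1-ETO replicate 1, and 14 without c-KIT(N822K) replicate 1; the other 5 genes were each lost in at least 1 such fit. In a limma fit of only these 6 arrays 0 genes were called, with 1886 at an unadjusted p under 0.05.

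Double-expressing cells differed from c-KIT(N822K) arrays at 2 genes. RUNX1T1 was higher (0.60 ± 0.07, adjusted p = 0.0194) and ALDOC was 1.62-fold lower (-0.69 ± 0.06, adjusted p = 0.00102). The p53 target CDKN1A had 0.38 ± 0.05 (adjusted p = 0.0584). ERK feedback genes were higher as a list (22 measured, median 0.042, adjusted p = 0.00829; adjusted p = 0.702 with an estimated correlation), with FOSL1 (0.29 ± 0.07) and PHLDA1 (0.18 ± 0.05) past the test over the list alone. That call was lost after quantile normalization (adjusted p = 0.0611) and without c-KIT(N822K) replicate 1 (0.308) or double-expressing replicate 2 (0.137). Cholesterol genes were lower (median -0.17, adjusted p = 6.62e-07; adjusted p = 0.398 with an estimated correlation), with 5 of 17 past the test over the list alone. There was 1 called gene without c-KIT(N822K) replicates 1 or 2 or double-expressing replicates 2 or 3, and there were 5 without RUNX1-ETO replicate 1, 6 without RUNX1-ETO replicate 3 and 57, 53 higher and 4 lower, without double-expressing replicate 1. ALDOC was called in each of these fits and RUNX1T1 in 8 of 12. Quantile normalization gave 31, 9 higher and 22 lower.

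The interaction asks whether both constructs together differ from the sum of their single effects, and 3 genes were called. MPO (2.33 ± 0.10, adjusted p = 6.71e-07) and PRG2 (1.25 ± 0.10, adjusted p = 0.000605) were lower with either construct, by less with both than the sum would give. MPO in double-expressing against RUNX1-ETO cells was -0.41 ± 0.07 (adjusted p = 0.0813; named after it was seen), and was called in 1 of 12 fits with 1 array left out, the one without RUNX1-ETO replicate 3. The sum of the single effects would put MPO at 4.12 and PRG2 at 5.37, under 5.84, the lowest value on any array, so the sum could not have been read for either gene. RNASE1 was lower with both constructs than the sum would give (-0.89 ± 0.09, adjusted p = 0.00454). Its values were not set against the floor in this way. The interactions of MPO, PRG2 and RNASE1 were called whichever single array was left out.

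Across all 18404 genes, the RUNX1-ETO effect in wild-type cells and in c-KIT(N822K) cells had a Pearson correlation of 0.326 and a Spearman correlation of 0.156. For the c-KIT(N822K) effect in wild-type and in RUNX1-ETO cells they were 0.548 and 0.455. Genes are not independent replicates. For simulated groups with no effect, the central ranges of the Pearson correlations were -0.784 to 0.754 and -0.785 to 0.754, so neither value lay outside chance. These ranges leave out the most extreme of 1000 draws at each end. The covariances were 0.00257 and 0.00581, against central simulated ranges of -0.00737 to 0.00719 and -0.00756 to 0.00779. Without RUNX1-ETO replicate 3 the first Pearson correlation was 0.0692, and without RUNX1-ETO replicate 2 it was 0.511, and without c-KIT(N822K) replicate 1 0.167; the other was 0.218 without c-KIT(N822K) replicate 1. The test of any difference among the 4 groups called 52 genes. Arrays were not grouped by label alone. Between-group differences held 35.8% of the variance. With 4 groups of 3 arrays, a part of such a share arises with no group effect at all, and that part was not taken off. Of the variance within groups, 54.0% lay on 1 axis. On it c-KIT(N822K) replicate 1 and RUNX1-ETO replicate 3 stood apart from c-KIT(N822K) replicate 3 and RUNX1-ETO replicates 1 and 2.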

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

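Most tests of the KIT, MPO and sterol patterns were chosen after the results were seen. The exception was the test of whether the decrease of sterol, glycolysis and hypoxia genes exceeded the sum of both constructs. Both constructs together differed from the sum of their single effects for RNASE1 (-0.89). Its values were not set against the floor of the arrays, so a part played by the floor is not excluded. MPO (2.33) and PRG2 (1.25) were called as well, but the sum would put them at 4.12 and 5.37, under the lowest value on any array (5.84), so these values do not show a departure from it. By camera with the preset correlation 10 lists were called for the same contrast, none of which was called with an estimated correlation. Their median interactions were 0.067 for STAT5 response genes, -0.14 for mitosis genes, -0.060 for monocyte genes and 0.097 for genes reported as induced by RUNX1-ETO. They were 0.082 for genes reported as repressed by RUNX1-ETO, -0.045 for interferon genes and -0.026 for glycolysis and hypoxia genes. For ribosomal proteins, histones and reference genes they were -0.29, -0.071 and -0.20. After quantile normalization the median of the ribosomal list was 0.0029 (adjusted p = 0.978). There were 18 such lists without c-KIT(N822K) replicate 1 and 20 without RUNX1-ETO replicate 3.

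Among the 13163 probe sets without a single gene symbol, which the comparisons did not use, 1 was called for c-KIT(N822K) against wild type, 1 for RUNX1-ETO against wild type, 28 for both constructs against wild type, 1 for the interaction and 3 for any difference.

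The KIT probe set was not raised on arrays labelled c-KIT(N822K). Its highest array lay 0.12 above the median of the 12, and its mean was at percentile 25.9 of all probe sets, so it may not read the introduced transcript. If so, it cannot show whether arrays were exchanged between the groups. The ERK feedback list, with a median of -0.027 in c-KIT(N822K) against wild type over members that went both ways, does not decide whether the labelled cells had little kinase activity. A biological explanation, weak expression of the introduced kinase, stays open as well.

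MPO and PRG2 were lower in all 3 transduced groups. With the within-group axis as a covariate, MPO in double-expressing against wild-type cells was -2.74 ± 0.07. MPO varied little within groups, and the covariate's slope comes from that spread. The covariate could therefore hardly have moved MPO, and this value does not decide on the axis. Loss of a granule-rich part of the cells would lower the other abundant granule transcripts; ELANE, PRTN3, AZU1 and CTSG had a median of 0.26 and a spread of 0.14 (SD of the 4). The MPO means of the 3 transduced groups ranged over 0.43, against a gap of 2.31 to wild type, so transduction, sorting or separate culture cannot be told apart from the constructs without an empty-vector group. A shared effect of both constructs may explain it too, and was not tested.

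In double-expressing against wild-type cells 5 of 17 cholesterol genes and 7 of 27 glycolysis and hypoxia genes were called lower. Both lists were called by camera with the preset correlation and by fry, but not by camera with an estimated correlation (adjusted p = 0.342 for each). Adjusted over the list alone, 2 glycolysis genes were higher. With the within-group axis as a covariate the cholesterol median was -0.25 (-0.31 without it, jackknife SE 0.0907). An axis that was the main cause would bring its size under 0.156. That bound was not much more than the SE away, so the axis is not excluded as the main cause. The median of the 5 called cholesterol genes was -0.71 with it and -0.80 without it (jackknife SE 0.0625), and all 5 were called with it. The median of the 7 called glycolysis and hypoxia genes was -0.67 with it and -0.82 without it (jackknife SE 0.0846). All 7 were called with it. Called genes vary little within groups, and the covariate's slope comes from that spread. It kept all 173 calls of this comparison. The covariate could therefore hardly have ended the decrease of the called genes, and their values do not decide on the axis. The median of all 27 glycolysis and hypoxia genes was -0.083 with the covariate and -0.073 without it. Its jackknife SE of 0.0997 was too wide to decide. The 12 called members had a median interaction of -0.17 (SD 0.12), but they had been picked for being lower in double-expressing cells, a difference that enters the interaction, so this value decides nothing. Over the full lists the median interaction by camera was -0.040 for cholesterol genes (adjusted p = 0.0668). For glycolysis and hypoxia genes it was -0.026 (adjusted p = 0.0415, and 0.702 with an estimated correlation). Culture density or medium was not tested.

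Other groupings of the arrays were counted for each number of called genes. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In c-KIT(N822K) against wild type, 1 split gave as many as the real 7, and the highest other gave 0. For RUNX1-ETO against wild type, 1 split reached the real 15 (highest other 0), and for both constructs against wild type 1 reached 173 (highest other 0). For double-expressing against RUNX1-ETO cells 1 reached 6 (highest other 1), and against c-KIT(N822K) arrays 2 reached 2 (highest other 21). Of 100 groupings of all arrays, 5 gave at least the 3 interaction calls (highest other 401), so chance was not excluded for that count. For any difference, 4 of 100 gave at least 52, the real one included, and the highest other gave 1889. A share so close to 0.05 from 100 sampled groupings does not exclude chance either. Such counts point to a structure of the arrays that the labels do not give.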

How the results depend on the processing

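No named gene past its threshold changed direction under any planned or added alternative, and the interaction kept MPO, PRG2 and RNASE1 under each alternative except a minimum log2 change of 1, which left MPO and PRG2. The 2 alternatives added after seeing the data were the joint removal of c-KIT(N822K) replicate 3 and RUNX1-ETO replicate 3 and the axis covariate. The signal of dim genes over background limits their fold changes. Unless a reason is given, the cause was not tested.

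Counts of called genes follow in the order c-KIT(N822K), RUNX1-ETO and both constructs against wild type, both against RUNX1-ETO, both against c-KIT(N822K), interaction, any difference; the reported counts are 7, 15, 173, 6, 2, 3 and 52. Quantile normalization gave 9, 35, 468, 37, 31, 4 and 136. Median centring gave 5, 9, 45, 1, 2, 3 and 15. Without the dimmest 50% the first count was 3, and with all probe sets the last was 26. A prior with trend and robust fitting gave 22, 58, 364, 38, 10, 6 and 181. Array weights gave 9598, 9480, 4331, 10403, 3679, 6139 and 16004; they put a weight of 19.5 on c-KIT(N822K) replicate 2 and 15.4 on RUNX1-ETO replicate 1, which makes the spread of those groups rest almost on 1 array. Fits of the compared arrays alone gave 2, 4, 1388, 0 and 3. An adjusted p of 0.01 gave 2, 7, 22, 2, 1, 3 and 11, and a minimum log2 change of 1 gave 2, 4, 5, 0, 0, 2 and 6, by construction fewer. Without c-KIT(N822K) replicate 3 and RUNX1-ETO replicate 3 there were 179, 293, 1076, 2404, 2, 3 and 2203; these arrays were picked for lying far from their groups, so their removal lowers the spread by construction. The axis covariate gave 35, 102, 678, 28, 46, 4 and 261; it is built from the same residuals it removes, which also lowers the spread.

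Leaving out 1 array gave ranges of 2 to 7, 6 to 64, 16 to 432, 1 to 204, 1 to 57, 3 to 3 and 10 to 159. The highest came without RUNX1-ETO replicate 3 for RUNX1-ETO and both against wild type, both against RUNX1-ETO, and any difference. Any difference also gave 101 without double-expressing replicate 1 and 79 without c-KIT(N822K) replicate 3, and 10, 12, 12, 13, 17, 17, 21 and 30 without double-expressing replicate 2, wild-type replicates 1 and 2, double-expressing replicate 3, RUNX1-ETO replicates 1 and 2, wild-type replicate 3 and c-KIT(N822K) replicate 2.

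With the replicate number as a block the counts were 2, 5, 35, 1, 2, 3 and 13. Arrays share a number but nothing shows pairing: 4 of 18 same-number pairs had residual correlations over 0.1, from -0.827 to 0.402, and 4 of 12 arrays correlated best with their own number.

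Lists called, for the 6 contrasts in that order, numbered 13, 15, 13, 15, 9 and 10. With an estimated correlation they numbered 0, 1, 0, 0, 0 and 0, and with fry 2, 5, 5, 0, 0 and 2. The cholesterol list, the glycolysis and hypoxia list and the MHC class II list stayed called by fry in both constructs against wild type. Fry also called primary granule genes there (adjusted p = 0.00215) and in c-KIT(N822K) against wild type (adjusted p = 0.00811), which camera had not called. The medians of the granule list in these comparisons were only -0.024 and 0.0099. Quantile normalization gave 5, 6 and 5 for the first, the fourth and the interaction. Without the dimmest 30% the first and the fourth gave 7 and 7. The interaction gave 17 without both arrays and 7 to 20 when 1 array was left out, and the axis covariate gave 8 for both against RUNX1-ETO.

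The repair genes in RUNX1-ETO against wild type (median -0.043) ranged from -0.066 to 0.049 when 1 array was left out, turned to 0.049 without both arrays, and were called at -0.049 with the axis covariate. In both against RUNX1-ETO (median -0.098, adjusted p = 0.00214) they ranged from -0.17 to -0.037. The call was lost with quantile normalization (-0.044), without the dimmest 30% (-0.099), with an estimated correlation (-0.098, adjusted p = 0.756) and with fry (-0.098), and the axis covariate turned it to 0.020. Mitosis genes in that comparison (median -0.19) were called by camera but not with an estimated correlation (adjusted p = 0.751), fry (0.665), quantile normalization (0.154) or that covariate (median -0.0051, 0.717). Reference genes in RUNX1-ETO against wild type (median 0.13; adjusted p = 0.395 with an estimated correlation) turned to -0.0068 with quantile normalization.

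Of the 15 genes called with RUNX1-ETO against wild type, 2 were called the opposite way in double-expressing against RUNX1-ETO cells. This became 5 of 35 with quantile normalization and 1 of 5 with the replicate block. When 1 array was left out the count was 1 to 15, the highest being 15 of 64 without RUNX1-ETO replicate 3. The correlations across genes ranged from 0.0692 to 0.511 for RUNX1-ETO and from 0.218 to 0.682 for c-KIT(N822K) when 1 array was left out.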

Other observations

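Other gene groups fixed before the data were examined are given here as values. Oxidative stress genes were higher with RUNX1-ETO than in wild type (20 measured, median 0.22, adjusted p = 6.66e-08; adjusted p = 0.342 with an estimated correlation), although CYBB, the 1 called member, was lower; MT2A (0.37 ± 0.09), FTL (0.24 ± 0.06) and HMOX1 (0.24 ± 0.07) were among the 4 higher adjusted over the list alone. After quantile normalization MT2A was at 0.074 and FTL at 0.056. BCL2 family genes were higher in double-expressing than in c-KIT(N822K) cells (15 measured, median 0.085, adjusted p = 0.0074; adjusted p = 0.342 with an estimated correlation, and 0.106 after quantile normalization), with the pro-apoptotic BAD (0.24 ± 0.06) past the test over the list alone. Mitosis genes had a median of -0.19 in double-expressing against RUNX1-ETO cells (29 measured, 0 called by limma and 1 lower at an unadjusted p under 0.05; adjusted p = 0.751 with an estimated correlation, and 0.154 after quantile normalization), among them TTK at -0.31 ± 0.13. With the array's place on the main within-group axis as a covariate the median was -0.0051 (adjusted p = 0.717), so the shift went with that axis.

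Markers of other cell types showed little. In both constructs against wild type the medians were 0.019 for mast cell, 0.012 for erythroid, 0.0046 for lymphocyte and 0.014 for fibroblast and epithelial genes, with adjusted p of 0.399, 0.586, 0.783 and 0.611. Stem cell genes (median 3.1e-05, adjusted p = 0.997), inflammatory genes (-0.00075, 0.763), replication genes (-0.020, 0.477), reference genes (-0.012, 0.545) and unfolded protein response genes (-0.069, 0.493) were not called there either. Histone genes (0.098, adjusted p = 0.00175) and MYC targets (0.14, 0.000485) were higher, with adjusted p of 0.577 and 0.702 with an estimated correlation. Of the 6 repair pathways in that comparison, homologous recombination (-0.17, adjusted p = 0.00164), Fanconi anaemia (-0.13, 0.0147) and nucleotide excision repair (-0.10, 0.0161) were lower, and end joining (-0.073, 0.135), base excision (-0.010, 0.791) and mismatch repair (-0.17, 0.0884) were not called; none of the 6 was called with an estimated correlation.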
